A study of Mus musculus with 4 samples.

How the data were processed

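Single-cell RNA sequencing of mouse lung was deposited as 4 libraries, 1 for each combination of genotype and treatment, and each library was a pool of cells from 5 mice aged 11 weeks. The groups were normoxia wild type (NW), normoxia FUNDC1 knockout (NK), HySu wild type (HSW) and HySu FUNDC1 knockout (HSK). HySu stands for hypoxia with 3 weekly doses of SU5416, an inhibitor of the VEGF receptor; control mice received vehicle and stayed in normoxia. Per the labels, fresh lungs were digested with enzymes, red cells were lysed, and cells were captured in a microwell chip for polyA RNA libraries sequenced as paired ends on a NovaSeq instrument. The labels give no sequencing batch and do not say in which cells the gene was deleted.

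The deposited matrices held a raw count of unique molecular identifiers (UMIs) for each gene and cell, as whole numbers without normalization. Upstream tools were, per the submitters' processing notes, cutadapt 1.17, STAR 2.6.1a, featureCounts 2.0.1 and Scanpy with genome builds GRCm38 and mm10; the notes give no order or settings. Each matrix held only cells above a minimum number of UMIs, and this minimum differed between libraries, at 3775 in NW, 3182 in NK, 4230 in HSW and 4726 in HSK. Shares of cells can therefore depend on where each library was trimmed.

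Cells with fewer than 200 genes or more than 20% mitochondrial UMIs were removed, which took 1 cell of NK and 1 cell of HSW. The 4 libraries were clustered together with scanpy 1.11.5, using 2000 highly variable genes, 40 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 1. Scrublet, run per library with an expected doublet share of 6%, called 4 cells in NW, 5 in NK, 31 in HSW and 39 in HSK, too few for libraries of this size, and clusters still held cells with marker genes of more than one lineage. A rule on mixed cells was therefore added: a cell was removed when a second lineage reached more than 0.15 of its reference level with at least 3 UMIs, a set of general leukocyte genes included. Several versions of this rule were tried after the clusters were seen. They were judged by the purity of the clusters and the number of cells left, before any ratio between libraries was computed. A level of 0.1 was given up because it left 45 endothelial cells in NW and marked part of a cluster of alveolar type 2 cells. The rule removed 24.5% of cells in NW, 31.8% in NK, 18.1% in HSW and 10.4% in HSK, so it acted unequally on the groups. The original plan, removal of Scrublet calls alone, is kept among the alternatives.

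Clusters were named from marker genes fixed in advance. A cluster took the class whose markers stood highest when at least 3 of them were detected, no other lineage reached 0.2 of its reference, and no other lineage had more markers among the 10 leading genes. Endothelial subtypes came from a clustering on subtype markers with 15 neighbours and 15 components; 1 sub-cluster led by haemoglobin genes stayed unnamed and was kept among vascular endothelial cells. These thresholds and the subtype clustering were set after the clusters were seen. Clusters that met no name were left out of the class comparisons, at 7.48% of kept cells in NW, 9.29% in NK, 4.32% in HSW and 4.04% in HSK. Alveolar and adventitial fibroblasts were summed as fibroblasts, a class that was also to hold myofibroblasts, but no cluster took that name.

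UMIs were summed over the cells of a class in each library and expressed as CPM, the usual scaling of counts by the total UMIs of that class. Ratios between libraries carry exact conditional-binomial (Clopper-Pearson) 95% intervals, shares of cells carry Clopper-Pearson 95% intervals, and levels carry exact Poisson 95% intervals. All these intervals cover counting error only. With 1 library per group there is no measure of the variation between mice or captures, so no p-value, standard error or number of changed genes is given. A gene at 0 UMIs in one library is given as a lower bound, computed against a floor of 3 counts in that library.

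For 26 gene lists, the median log2 ratio over members with at least 20 UMIs in the pair was computed with 0.5 UMI added to each count. Its interval came from 2000 Poisson draws, and it was placed among 10000 random lists matched on expression in 10 bins; percentiles below refer to this ranking. The difference of the HySu effects was log2(HSK/NK) minus log2(HSW/NW), with an interval from 2000 Poisson draws. Named genes followed a size rule: in endothelial cells, the 8 largest and 8 smallest ratios per pair among genes with at least 30 UMIs, at least 50 CPM in one library, an interval that excludes 1 and a level of at least 33.3% of that in the highest class. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and unnamed predicted genes were left out. In fibroblasts, monocytes and macrophages the rule took 3 genes per direction for HSW against NW and for HSK against HSW, with at least 50 cells of the class in each library. Up to 4 members of each list described and 5 genes per direction of the difference were named, and Fundc1 was always named. A gene that this rule takes is not reported here. Groups, comparisons, gene lists, markers, named-gene rules and most alternatives were fixed before the data were examined. Which list stands for each endothelial comparison in the account of alternatives was chosen after the values were seen.

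The alternatives fixed in advance were TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, ribosomal and haemoglobin genes, the mean of the CPM of single cells, subtraction of free RNA, a minimum of 100 UMIs, a stricter cell filter (500 genes, 10% mitochondrial UMIs), doublets kept, marker gating, clustering at resolution 0.5 and 2, and thinning of cells to the 25th percentile of UMIs. Alternatives added after the data were seen were the level of 0.1 for mixed cells, the rule without the leukocyte set, Scrublet calls alone, a common minimum of 4726 UMIs, mixed cells in the denominator of shares, equal weights for endothelial subtypes without a minimum number of cells, and removal of an unnamed endothelial sub-cluster. In the equal weighting, the unnamed sub-cluster was counted with general capillary cells, so a shift between these was not removed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 were used. The calculation was checked on simulated data with the depth of these libraries: intervals of unchanged genes held the true ratio in 96.3% of 7739 genes for HSW against NW and 96.0% of 4756 genes for NK against NW, a 2-fold increase was seen in 70.0% and 66.7% of raised genes, and a 4-fold increase in 100%. The simulated counts were Poisson draws, the model that the intervals assume, without variation between cells. Coverage near 95% was therefore built in, and the intervals of ratios do not cover the sampling of cells. Of 200 unchanged lists, 6.5% fell outside the central 95% of random lists for HSW against NW, 3.0% for NK against NW, 2.5% for HSK against HSW and 7.5% for HSK against NK. Mural cells, with 17 cells in NW, 12 in NK, 13 in HSW and 13 in HSK, were too few to compare.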

Results

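The deposited data were single-cell transcriptomes of mouse lung from 4 groups in a 2 by 2 design of FUNDC1 genotype and HySu, a mouse model of pulmonary hypertension. Each group had 1 library, so no value below has a replicate, and every interval in square brackets is a 95% interval of counting error only. NW held 7649 cells with 62747087 UMIs, NK 9164 cells with 63501686, HSW 5041 cells with 45589625 and HSK 4128 cells with 41308071. After removal of mixed cells, 5774, 6252, 4121 and 3692 cells were kept, with median UMIs per cell of 6198.5, 5346.5, 7131 and 7843. Vascular endothelial cells, the class that the series title points to, numbered 50 in NW, 113 in NK, 274 in HSW and 128 in HSK, with 314342, 498500, 1729795 and 865868 UMIs. The 50 cells of NW limit the precision of each ratio against that library.

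The first question was whether Fundc1, which encodes a mitophagy receptor of the outer mitochondrial membrane, was lost in the knockout libraries, and in which cells. Over all kept cells, the Fundc1 level was 44.0 CPM [42.1, 45.9] in NW and 1.03 [0.752, 1.38] in NK, 42.6-fold lower [31.8, 58.6]. Under HySu it was 38.8 CPM [36.8, 40.8] in HSW and 0.244 [0.112, 0.463] in HSK, 159-fold lower [83.5, 348.5]. In endothelial cells 7 UMIs were seen in NW, 1 in NK, 80 in HSW and 0 in HSK, so HSK was at least 13.4-fold lower than HSW, and the NK to NW ratio was 0.0901 [0.00200, 0.701]. Fundc1 was low outside the endothelium as well. The level in alveolar macrophages was 51.8 CPM in NW, 1.03 in NK, 53.02 in HSW and 0.140 in HSK. Alveolar type 2 (AT2) cells had 29.2 CPM in NW, 0.662 in NK, 30.5 in HSW and 0.108 in HSK. Fibroblasts had 41 UMIs in NW and 0 in NK, at least 15.9-fold lower, and an HSK to HSW ratio of 0.0245 [0.000606, 0.144]. Classical monocytes had an NK to NW ratio of 0.0355, and 218 UMIs in HSW against 0 in HSK, at least 20.7-fold lower. After thinning to 4869 UMIs per cell, which left out 1579, 2682, 577 and 120 cells, 15.9% of cells in NW, 0.420% in NK, 14.5% in HSW and 0.112% in HSK had a Fundc1 UMI; without thinning the shares were 23.1%, 0.528%, 23.1% and 0.217%. HySu in wild type left the level over all cells at 0.882 [0.824, 0.944] of that in NW, and in endothelial cells the HSW to NW ratio was 2.08 [0.963, 5.33].

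**Figure D1:**
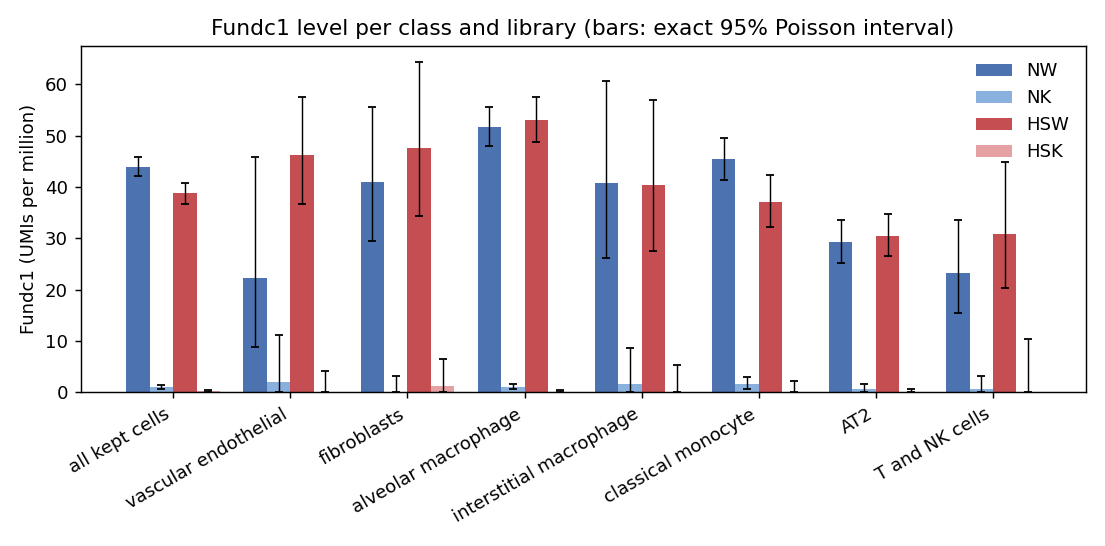
Fundc1 level, in CPM, over all kept cells and in 7 classes, with a bar for each of the 4 libraries and lines for the 95% Poisson interval. Over all kept cells NW stands at 44.0 and HSW at 38.8, against 1.03 in NK and 0.244 in HSK.

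The make-up of the suspensions differed between the groups. Vascular endothelial cells made up 0.866% [0.643, 1.14] of kept cells in NW, 1.81% [1.49, 2.17] in NK, 6.65% [5.91, 7.45] in HSW and 3.47% [2.90, 4.11] in HSK, a HSW to NW ratio of 7.68 [5.66, 10.6]. Classical monocytes were 29.2% [28.0, 30.4] in NW, 18.0% [17.0, 19.0] in NK, 21.0% [19.7, 22.2] in HSW and 6.74% [5.96, 7.60] in HSK. Non-classical monocytes, which patrol the vessel wall, went from 5.04% in NW and 2.90% in NK to 1.504% in HSW and 0.108% [0.0295, 0.277] in HSK. Alveolar macrophages made up 19.0%, 25.3%, 21.1% and 33.8% in the same order, and AT2 cells 18.8% in NW, 19.0% in NK, 23% in HSW and 33.0% in HSK. Fibroblasts stayed between 3.12% and 3.87%. With doublets kept, the ratio of the endothelial share between HSW and NW was 4.54 rather than 7.68. Digestion, red cell lysis, capture and the unequal UMI minimum of the libraries can set such shares, and 1 library per group does not separate these from the treatment.

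**Figure D2:**
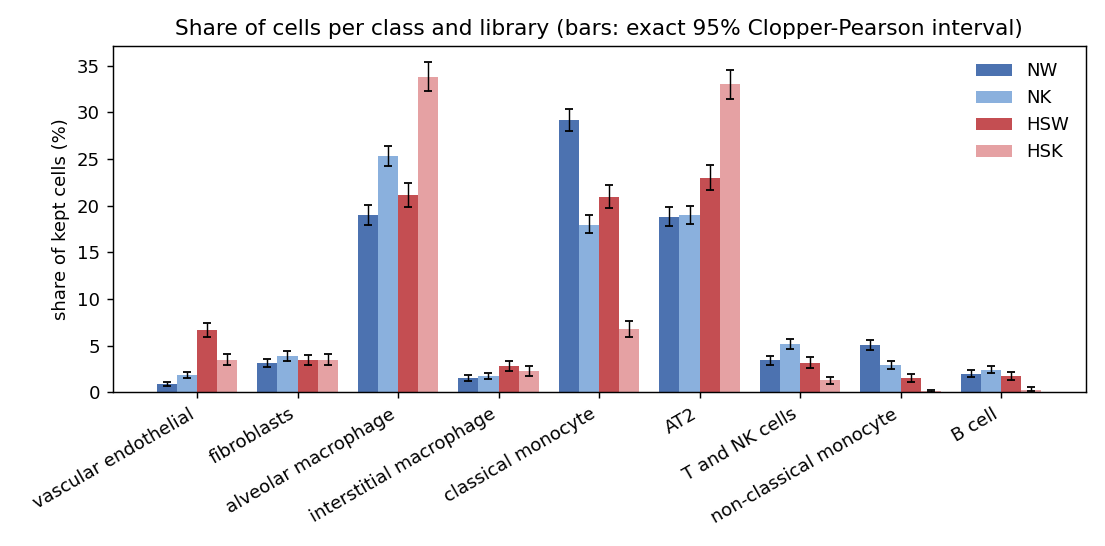
Share of kept cells, in percent, of 9 cell classes in each of the 4 libraries, with lines for the 95% Clopper-Pearson interval. The endothelial share is 0.866% in NW and 6.65% in HSW, and the classical monocyte share is 29.2% in NW and 6.74% in HSK.

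HSW against NW asked what HySu did in wild-type endothelial cells. Cyp1b1, a cytochrome P450, was 342 times as high [94.6, 2825], with 3764 UMIs against 2, and Cyp1a1, a cytochrome of the same family, 10.3 times [8.99, 11.8]. Ahrr, the repressor of the aryl hydrocarbon receptor, had 100 UMIs against 0, at least 6.06-fold higher. Nqo1, a quinone reductase, was 26.7 times as high [7.33, 222] and Gstp1, a glutathione transferase, 6.42 times [4.35, 9.88]. Cmtm8 (7.27), Vldlr, a lipoprotein receptor (7.09 [2.37, 34.9]), and Mal (6.06 [2.01, 29.9]) completed the 8 genes with the largest ratios. Cyp1b1, Cyp1a1, Ahrr and Nqo1 are known targets of the aryl hydrocarbon receptor, for which no list was fixed in advance. The lowest ratios included Fabp4, a fatty acid carrier of capillary endothelium (0.0515 [0.0282, 0.0894]), the protocadherin Pcdh7 (0.0748), Selp, the leukocyte adhesion molecule P-selectin (0.0779 [0.0361, 0.158]), Pgm5 (0.0795), Chn2 (0.0948), Fgl2 (0.101), the integrin Itgb4 (0.123) and Klhl6 (0.126). Cyp1a1 was also higher in other classes, at 5.09 times in fibroblasts, 21.4 in alveolar macrophages and 21.3 in AT2 cells. Its level in HSW was highest in endothelial cells, at 7035 CPM against 64.8 in the next class. Endothelial identity genes also read higher in alveolar macrophages and AT2 cells of HSW, so RNA from endothelial cells is not excluded there.

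Among the gene lists in the same comparison, genes of antigen presentation were higher. The MHC class I list had a median log2 ratio of 0.54 [0.31, 0.64], with 11 of 15 measured members higher (H2-Q4 2.02 times, B2m 1.59 times), and MHC class II 0.75 [0.48, 0.97], with 7 of 8 higher (H2-Aa 2.09 times, Cd74 1.97 times). The apoptosis and p53 list stood at 0.64 [0.31, 0.87], with 15 of 21 higher, among them Bax, a pore-forming death effector (3.11 times). The antioxidant list stood at 0.21 [0.06, 0.39], with 17 of 24 higher, led by Nqo1, Srxn1 (3.27 times) and Txnrd1 (2.07 times), while the peroxidase Gpx3 was lower (0.323). Leukocyte adhesion genes were lower, at -0.71 [-0.83, -0.21] with 12 of 18 lower, including Selp and Vcam1 (0.335), although the chemokine Cxcl12 was higher (2.17 times). Extracellular matrix genes were lower, at -0.43 [-0.76, -0.13] with 15 of 23 lower (Thbs1 0.1497, Bgn 0.329), as were mesenchymal transition genes, at -0.59 [-0.85, -0.25] with 12 of 17 lower (Fn1 0.430). The matrix list lay below the range of random lists in alveolar macrophages (-0.48) and AT2 cells (-0.89) as well, and the mesenchymal list in interstitial macrophages (-0.815), classical monocytes (-0.71), AT2 cells (-1.04) and T and NK cells (-0.85). In endothelial cells the mesenchymal list moved to 0.0213 with thinned cells. Mitochondrially encoded respiratory chain (OXPHOS) genes were higher, at 0.87 [0.77, 0.96], with 6 of 7 higher, and nuclear-encoded ones stood at 0.16 [0.10, 0.25]; the mitochondrially encoded genes were also above 0 in 8 of 8 other classes. All the lists of this paragraph lay outside the central 95% of random lists.

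The cell cycle list stood at 1.47 [1.04, 2.59] in the same comparison, with 18 of 22 members higher, but this value was not firm. Of its members, 7 had 0 UMIs in one library, and with these at their bound the median was 0.73. Mki67, a proliferation marker, had 114 UMIs against 0, at least 6.91-fold higher, and Cenpf 86 against 0, at least 5.21-fold. Cells with at least 3 cell cycle markers made up 6.0% [1.26, 16.6] of endothelial cells in NW (3 of 50) and 5.11% [2.82, 8.42] in HSW (14 of 274). With Scrublet calls alone removed, as first planned, the median was -0.18. Lists that lay inside the range of random lists were mitophagy (0.10 [-0.05, 0.31]), mitochondrial dynamics (-0.12), HIF targets and glycolysis (-0.08 [-0.19, 0.20]), the mitochondrial and integrated stress response (-0.21), heritable pulmonary hypertension genes and the BMP pathway (0.13), vasoactive signalling (-0.15), endothelial identity (-0.12), angiogenesis (-0.15), the interferon response (-0.03), cGAS-STING and inflammasome genes (0.05), immediate early genes (-0.17), ribosomal protein genes (0.06), contractile genes (-0.41), macrophage inflammatory and repair genes (-0.10) and sex-linked genes (-0.41). Haemoglobin and surfactant transcripts, a measure of RNA from other cells, stood at 0.30, at the 97.8 percentile. TMM scaling moved the median of all genes in this comparison from -0.11 to 0.08 and in HSK against NK from -0.19 to 0.03, so values within such a shift carry no direction.

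NK against NW asked what the knockout did under normoxia. The largest ratios were those of Per1, a circadian clock gene induced by glucocorticoids (8.32 [3.39, 26.5]), Arl15 (7.19), Mmd (6.10 [1.89, 31.3]), Csrnp1 (5.41 [3.10, 10.2]), Ddit4, a stress-induced inhibitor of mTORC1 (5.28 [2.53, 12.7]), Seh1l (4.57), Vrk3 (4.54) and Cmtm8 (4.41). The smallest were those of Faf1 (0.219 [0.0848, 0.508]), Hhip, an inhibitor of hedgehog signalling (0.237), Myof (0.243 [0.142, 0.404]), Pgm5 (0.256), Dcaf11 (0.261), Srek1ip1 (0.274), Erh (0.289) and Lpin2 (0.291). Per1 and Ddit4 were higher outside the endothelium too: Per1 was 1.53 times as high in alveolar macrophages and 2.57 times in AT2 cells, and Ddit4 3.50 times in fibroblasts and 12.03 times [3.83, 60.9] in interstitial macrophages. Heritable pulmonary hypertension and BMP pathway genes were higher, with a median log2 ratio of 0.36 [0.14, 0.53], the 99.9 percentile of random lists and 14 of 18 members higher. Among them were Hey1, a Notch and BMP target (3.70 times [2.13, 6.89]), Sox17, an arterial transcription factor (2.12 times), and the inhibitory Smad7 (1.77 times). Hey1 is a leading gene of a general capillary sub-cluster. General capillary cells made up 16.0% [7.17, 29.1] of endothelial cells in NW and 31.0% [22.6, 40.4] in NK, intervals that overlap. With subtypes weighted equally the list stood at 0.23. The list also lay above the range of random lists in classical monocytes (0.26), non-classical monocytes (0.48) and T and NK cells (0.41).

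Mitochondrially encoded OXPHOS genes were lower in NK, at -0.37 [-0.63, -0.30], with 7 of 7 members lower (mt-Cytb 0.603, mt-Co1 0.687). Nuclear-encoded OXPHOS genes stood at -0.12 [-0.21, -0.06] with 52 of 75 lower, and ribosomal protein genes at -0.30 [-0.37, -0.28] with 55 of 58 lower. Each of these 3 lists was below 0 in 8 of 8 other classes, with mitochondrially encoded medians there from -0.73 to -0.38, and with thinned cells the endothelial median of these genes was -0.67. Mitophagy genes were at -0.01 [-0.22, 0.12] and mitochondrial dynamics genes at 0.02 [-0.40, 0.31], inside the range of random lists, and a change of these lists larger than the intervals was not detected. Mesenchymal transition (-0.34 [-0.53, 0.00]) and leukocyte adhesion genes (-0.33 [-0.45, 0.10]) had intervals that reached 0. This was the comparison with the fewest UMIs, and only 6 cell cycle genes could be measured in it (0.14).

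HSK against HSW asked what the knockout did under HySu. Fabp4 was 18.2 times as high in HSK [11.0, 32.1], the largest ratio. It was also higher in interstitial macrophages (16.4 times), fibroblasts (3.38 times) and AT2 cells (2.01 times). In alveolar macrophages it was unchanged (0.995 [0.955, 1.04]), and in classical monocytes it was 1.45 times [0.674, 2.93]. Within the endothelium the Fabp4 ratio rested on 1 unnamed sub-cluster, which held 20.4% of endothelial cells in HSW and 26.6% in HSK. Without it the log2 ratio of Fabp4 was -2.405, and that of Cenpf 0.47 rather than 1.05. With the sub-cluster included, Fabp4 had 17 UMIs in HSW, so its value without the sub-cluster rests on few UMIs. The leading genes of this sub-cluster were Fabp4 and genes of red cells (Hba-a2, Hbb-bs), of platelets (Pf4) and of the cell cycle (Ube2c, Cenpf). It was kept in the class because its cluster was named endothelial, and its general capillary markers stood at 0.723 of the highest sub-cluster. Prc1, an organiser of the spindle midzone, came next at 3.38 times [2.37, 4.86]. Casp8ap2 (2.15), the noradrenaline transporter Slc6a2, a venous marker (2.15 [1.66, 2.77]), Wtap (2.14), Tomm40 of the mitochondrial import pore (2.08), the kinetochore protein gene Cenpf (2.07 [1.52, 2.81]) and Thap7 (2.00) were the other high ratios. The lowest were Tnrc6a (0.421), Car2, a carbonic anhydrase (0.442 [0.311, 0.615]), Hid1 (0.449), Fam43a (0.451), Dhx40 (0.466), Dll4, a Notch ligand of sprouting endothelium (0.472 [0.330, 0.661]), Efr3a (0.474) and Lars (0.477).

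In the same comparison, lists of vascular growth and identity were lower in HSK. Angiogenesis and capillary repair genes stood at -0.19 [-0.34, -0.14], with 20 of 25 lower, among them Angpt2 (0.465), Aplnr (0.493), Dll4 and Sparcl1 (0.567). Endothelial identity genes stood at -0.13 [-0.20, -0.07] with 19 of 25 lower (Sox18 0.605), although Klf2, a gene induced by flow, was higher (1.54 times). Heritable pulmonary hypertension and BMP pathway genes stood at -0.15 [-0.26, -0.07] with 13 of 19 lower, including Smad6 (0.552), Hey1 (0.567) and Sox17 (0.718). Aplnr, Sparcl1 and Hey1 were among the leading genes of the general capillary sub-clusters. These sub-clusters held 36.1% of endothelial cells in HSW and 24.2% in HSK. With subtypes weighted equally the angiogenesis list stood at -0.21 and the pulmonary hypertension list at -0.13. The unnamed sub-cluster was counted as general capillary there, so a shift between these was not removed. Immune lists were lower as well: the interferon response was at -0.27 [-0.38, -0.13] with 28 of 33 lower (Ifit3b 0.400, Stat2 0.599), and MHC class I at -0.24 [-0.30, -0.14] with 15 of 16 lower (H2-Q7 0.767). MHC class I was below 0 in 5 of 5 other classes and the interferon list in 4 of 5. Antioxidant genes were higher, at 0.22 [0.09, 0.28] with 21 of 25 higher (Txnrd1 1.39 times, Prdx1 1.36 times), and so were nuclear-encoded OXPHOS (0.13 [0.10, 0.18], 54 of 75), ribosomal (0.15, 55 of 58) and immediate early genes (0.17 [0.10, 0.26], 20 of 25). Nuclear-encoded OXPHOS genes were above 0 in 5 of 5 other classes. Mitophagy genes (0.03 [-0.11, 0.11]), mitochondrial dynamics genes (-0.01), mitochondrially encoded OXPHOS genes (-0.06) and HIF targets (-0.02) lay inside the range of random lists.

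The cell cycle list stood at 0.76 [0.50, 0.92] in HSK against HSW, with 21 of 25 members higher, among them the mitotic genes Cenpe (3.47 times [1.92, 6.46]), Ube2c (2.75 times [2.08, 3.65]), Tpx2 (2.62 times) and Cenpa (2.55 times). It also lay above the range of random lists in alveolar macrophages (0.61) and classical monocytes (0.40). Cycling cells made up 5.11% [2.82, 8.42] of endothelial cells in HSW and 7.81% [3.81, 13.9] in HSK, intervals that overlap, and with Scrublet calls alone removed the median was 0.11. Transcripts of other cells moved in the same direction, with haemoglobin and surfactant genes at 0.86 [0.69, 1.00] and macrophage genes at 0.55 [0.21, 0.74] in endothelial cells of HSK; the macrophage list was at -0.17 with Scrublet calls alone removed.

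HSK against NK asked what HySu did in the knockout. Cyp1b1 led again, at 320.3 times [109, 1555], and Cenpf had 89 UMIs against 0, at least 17.1-fold higher. Nqo1 was 102 times as high [18.1, 4047], Prc1 25.3 times [6.81, 212], Gstp1 15.0 times [10.2, 22.9] and Vldlr 6.62 times. Gstp-ps, a near copy of Gstp1 whose reads may not be separable from it, was 6.05 times as high, and Cyp1a1 5.45 times [5.02, 5.93]. The lowest ratios were those of Cyp26b1, which breaks down retinoic acid (0.0823 [0.0523, 0.125]), Fibin (0.131), Atp13a3, a polyamine transporter gene linked to heritable pulmonary hypertension (0.134 [0.05999, 0.271]), Usp37 (0.185), Gtpbp6 (0.199), Amigo2 (0.1996), Cdk6 (0.1997) and Armcx4 (0.221). Angiogenesis genes were lower, at -0.55 [-0.77, -0.46] with 21 of 25 lower (Cxcr4 0.262, Aplnr 0.370, Dll4 0.381, Plvap 0.399). The list of heritable pulmonary hypertension genes and the BMP pathway stood at -0.45 [-0.57, -0.33] with 14 of 18 lower. Among them were the BMP receptor gene Bmpr2 (0.452 [0.409, 0.499]), Hey1 (0.412) and Smad6 (0.432). In 5 of 5 other classes, both this list (-0.75 to -0.11) and the angiogenesis list (-1.27 to -0.06) were below 0 too. Endothelial identity genes stood at -0.35 [-0.42, -0.26] with 20 of 25 lower (S1pr1 0.473, Nos3 0.485), while Icam2 was higher (1.91 times); with doublets kept this list was at 0.0360.

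Mitophagy genes were higher in HSK than NK, at 0.38 [0.11, 0.50], the 99.8 percentile of random lists with 16 of 25 higher. The difference from the HySu effect in wild type was 0.12 [-0.10, 0.31], an interval that held 0. Higher members included the hypoxia-induced receptor gene Bnip3 (2.13 times [1.13, 4.28]), Tomm7 (1.88 times) and Gabarapl1 (1.82 times), while Ulk1, a kinase that starts autophagy, was lower (0.489). Mitochondrially encoded OXPHOS (1.26 [1.18, 1.38]), nuclear-encoded OXPHOS (0.44 [0.38, 0.54]) and ribosomal genes (0.52) were higher, as they were in 5 of 5 other classes. Antioxidant genes stood at 0.33 [0.24, 0.59] with 18 of 24 higher, and apoptosis and p53 genes at 0.46 [0.18, 0.60] with 12 of 20 higher, led by the stress cytokine Gdf15 (9.40 times [4.17, 26.3]) and Casp8 (3.29 times). The cell cycle list stood at 2.43 [1.93, 4.09], or 2.37 with 5 members at their bound, with 18 of 21 higher (Ube2c 71.4 times [12.6, 2842]). Cycling cells made up 0.885% [0.0224, 4.83] of endothelial cells in NK (1 of 113) against 7.81% in HSK. These shares were not corrected for depth, and median UMIs of endothelial cells were 4013 in NK and 5968.5 in HSK. The median was 1.16 without the unnamed sub-cluster and 0.75 with at least 100 UMIs. With Scrublet calls alone removed it stood at -0.93, and the log2 ratios of Cenpf and Prc1 at -1.20 and -0.15. Haemoglobin and surfactant genes were at 1.31 in this comparison.

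**Figure D3:**
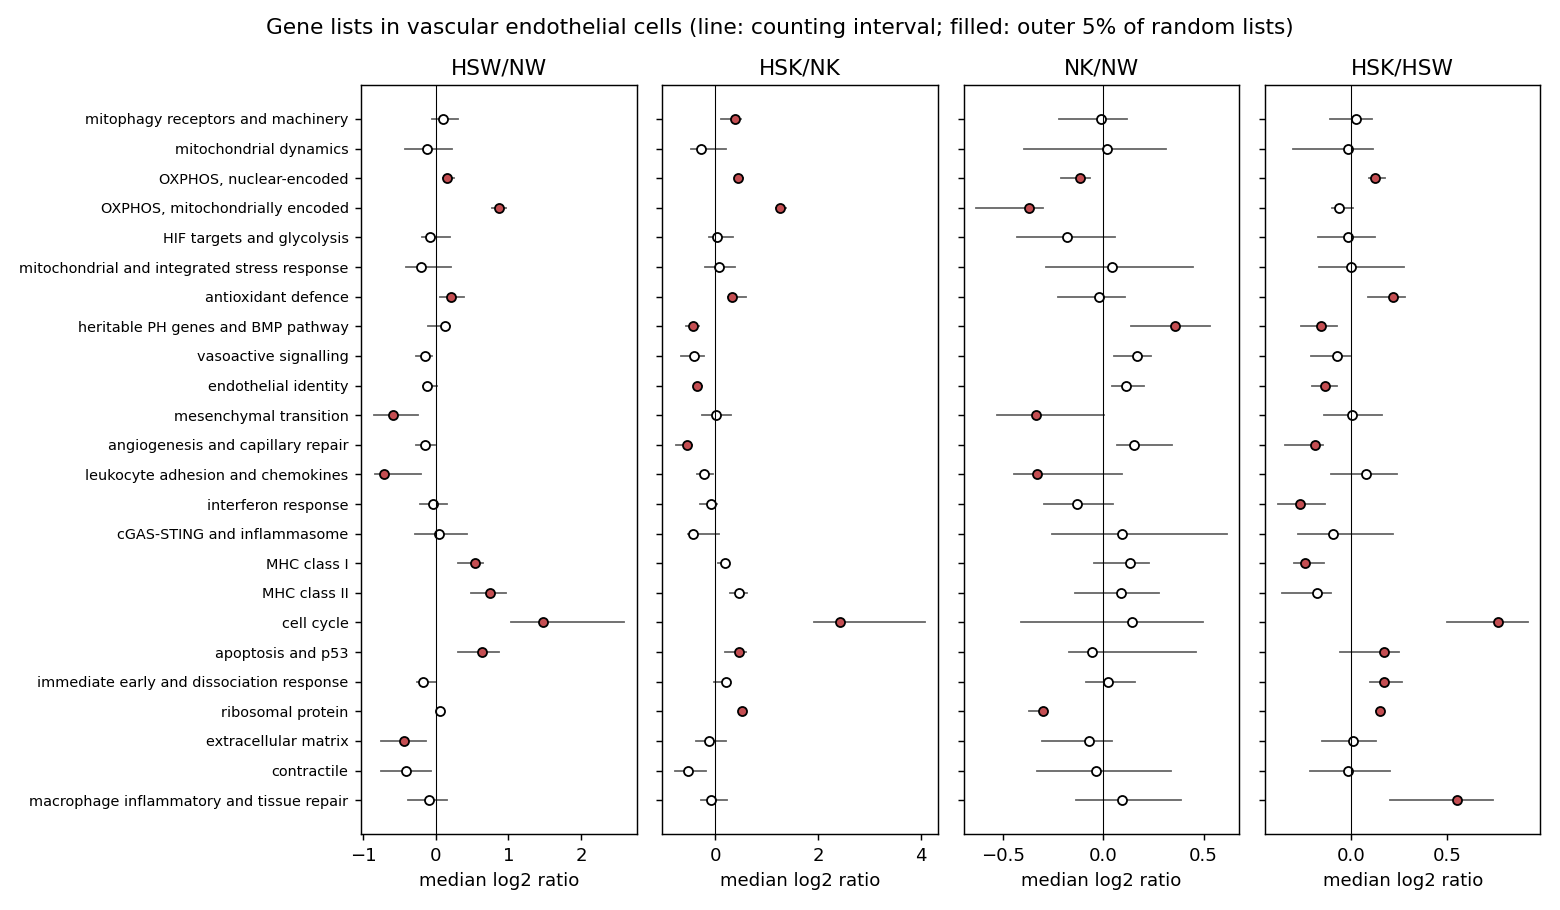
Median log2 ratio of 24 gene lists in vascular endothelial cells, in a panel for each of the 4 comparisons with its own scale, with lines for the counting interval. Filled points lie outside the central 95% of random lists; the cell cycle list stands at 1.47 in HSW against NW and 2.43 in HSK against NK, and both turn negative with Scrublet calls alone removed.

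The 2 by 2 design also asks whether HySu acted differently in the knockout. Across 6466 genes, the log2 HySu ratios of both genotypes were correlated in endothelial cells (Pearson r 0.453, Spearman rho 0.379). The log2 knockout ratios under normoxia and under HySu were not (r -0.06, rho -0.08 over 5041 genes); genes are not independent replicates. The largest differences of the HySu effect, log2(HSK/NK) minus log2(HSW/NW), were those of Fabp4 (5.85 [4.99, 6.97]), Srek1ip1 (2.61), Mzt2 (2.47) and Sik1 (2.43), and the most negative those of Arl15 (-3.12), Mmd (-2.89), Hey1 (-2.66 [-3.61, -1.86]), Msantd4 (-2.39) and Wdr43 (-2.39). Without the unnamed sub-cluster the Fabp4 difference was -0.76, a value that rests on few UMIs. Mal, at 0 UMIs in NK, had a difference of 3.26 with 0.5 UMI added but 0.45 with that count at its bound. Of the lists, the check on haemoglobin and surfactant transcripts had the largest difference (0.73 [0.53, 0.83]). Angiogenesis had the most negative difference (-0.65 [-0.79, -0.39]), with MHC class II (-0.48 [-0.58, -0.01]), heritable pulmonary hypertension and BMP pathway genes (-0.37 [-0.53, -0.22]), MHC class I (-0.36 [-0.49, -0.14]), endothelial identity (-0.19 [-0.35, -0.12]) and vasoactive signalling (-0.10 [-0.35, -0.02]) also below 0. Ribosomal (0.45), mitochondrially encoded OXPHOS (0.41), nuclear-encoded OXPHOS (0.28) and antioxidant genes (0.23 [0.06, 0.48]) were above 0. The intervals of the cell cycle list (0.48 [-0.01, 1.26]) and the mitophagy list (0.12 [-0.10, 0.31]), among others, held 0.

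Endothelial subtypes were too few in NW for separate comparisons of expression, so only their shares are given. Venous cells made up 28.0% [16.2, 42.5] of endothelial cells in NW (14 cells), 17.7% in NK, 9.85% [6.60, 14.0] in HSW and 10.9% in HSK. General capillary cells made up 16.0% [7.17, 29.1] in NW (8 cells), 31.0% in NK, 36.1% [30.4, 42.1] in HSW and 24.2% in HSK. The HSW to NW ratio of this share, 2.26 [1.10, 5.38], was 0 under the mixed-cell rule without leukocyte genes, so its direction is not firm. Aerocytes, the capillary cells of gas exchange, were 34.0%, 31.0%, 26.3% and 32.0%, and arterial cells 14.0%, 9.73%, 7.30% and 6.25%, with overlapping intervals. The lower share of venous cells stands beside the lower Selp and Vcam1 of HSW, which are markers of veins. Both genes were among the markers used to cluster the subtypes, so this share and these levels are not independent. Aplnr and Hey1 were among those markers too.

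Fibroblasts, compared because vessel walls are remodelled in this model, had higher Saa3, an acute phase protein gene (68.8 times [33.1, 172]), Mlana (19.6 times [6.35, 98.1]) and the chemokine gene Ccl8 (11.0 times [7.03, 18.2]) in HSW than NW. Hhip (0.173), Acta2, smooth muscle actin (0.174 [0.113, 0.260]), and Srf, a regulator of contractile genes (0.182), were lowest. The contractile list was lower, at -0.70 [-0.91, -0.42] with 0 of 12 members higher, as were immediate early (-0.59 [-0.73, -0.46]) and vasoactive genes (-0.62 [-0.71, -0.30]). Outside the endothelium, fibroblasts included, contractile medians were below 0 in 6 of 6 classes, immediate early in 8 of 8 and vasoactive in 6 of 8. In HSK against HSW the direction was the opposite for contractile genes. Thbs4, a matrix glycoprotein gene, had 115 UMIs against 0, at least 39.5-fold higher, Acta2 was 2.68 times as high [1.71, 4.31] and Mustn1 2.57 times. The contractile list stood at 0.18 [0.09, 0.35] with 9 of 11 higher, matrix genes at 0.22 [0.12, 0.24] with 26 of 40 higher, and mesenchymal transition genes at 0.21 [0.14, 0.29] with 18 of 23 higher. Matrix medians were above 0 in 5 of 5 classes outside the endothelium, fibroblasts included, from 0.22 to 0.46. Contractile and mesenchymal medians were each above 0 in 4 of 5, so these shifts were not particular to fibroblasts. Haemoglobin and surfactant transcripts moved alongside in fibroblasts, at -0.68 in HSW against NW and 0.99 [0.805, 1.08] in HSK against HSW, with 6 of 6 higher in the latter. Atf7 (0.313), Zfp36l2 (0.349) and the tissue factor gene F3 (0.417 [0.310, 0.555]) had the lowest ratios, and the log2 ratio of F3 was 0.37 under the mixed-cell rule without leukocyte genes. The interferon list stood at -0.28 [-0.49, -0.17] with 21 of 25 lower (Isg15 0.363). Both fibroblast comparisons also carry a change in make-up of the class. Alveolar fibroblasts were 101 of its 180 cells in NW, 57 of 141 in HSW and 68 of 129 in HSK.

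Interstitial macrophages had higher genes of tissue repair under HySu. In HSW against NW, the macrophage inflammatory and repair list stood at 0.85 [0.72, 0.94] with 24 of 31 higher, including Arg1, an arginase (93.7 times [16.5, 3730], 126 UMIs against 1), the cathepsin gene Ctsk (132 times [23.3, 5228], 177 UMIs against 1), Gpnmb (23.2 times [12.1, 51.3]) and the osteopontin gene Spp1 (8.59 times). Ctsk was 87.9 times as high [15.4, 3510] in NK as in NW, so its HySu ratio rests on a low count in NW. A gene listed as Mcub_2 in the files, whose identifier belongs to Areg, the amphiregulin gene, in GENCODE vM21, had 56 UMIs against 0, at least 13.9-fold higher. The chemokine genes Cxcl13 (0.132 [0.0997, 0.171]) and Cxcl9 (0.135) and the cell cycle regulator E2f1 (0.124) were lowest, and the cell cycle list stood at -1.95 [-2.36, -1.34] with 0 of 8 members higher (-1.02 with each cell weighted equally). In HSK against HSW, Fabp4 was 16.4 times as high [8.92, 33.6], Ankrd55 15.0 times [4.78, 76.1] and Mfge8, which bridges dying cells to phagocytes, 11.1 times [8.58, 14.6]; Spp1 was 7.18 times and Arg1 4.79 times as high, but the inflammatory and repair list as a whole stayed inside the range of random lists, at 0.09 [-0.07, 0.22] with 16 of 32 higher. Haemoglobin and surfactant transcripts were higher in these cells as well (0.47 [0.33, 0.59]). Cxcl13 (0.0526 [0.0106, 0.161]), Ocstamp (0.203) and Ccl12 (0.223 [0.182, 0.271]) were lowest. The interferon (-0.38 [-0.73, -0.23]), MHC class II (-0.37, 8 of 10 lower) and leukocyte adhesion lists (-0.43 [-0.55, -0.24]) were lower.

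Alveolar macrophages had lower cell cycle genes in HSW than NW, at -0.84 [-1.05, -0.72] with 23 of 26 lower (Mcm5 0.311, Mcm7 0.442), and lower genes of the integrated stress response, at -0.53 [-0.61, -0.43] with 19 of 23 lower (Trib3 0.155, Asns 0.205). Spag11b (9.15 times [7.45, 11.3]), Supt4a (1.95 times) and Tyrobp (1.94 times) had the largest ratios and the neutrophil chemokine gene Cxcl3 the lowest (0.183 [0.155, 0.215]). In HSK against HSW, the cell cycle (0.61 [0.44, 0.74], 24 of 26) and matrix lists (0.45 [0.22, 0.61], 22 of 29) were higher, and so were haemoglobin and surfactant transcripts (0.71 [0.66, 0.76]). Per1 (1.66 times), Car4 (1.46 times) and Ftl1 (1.45 times) led, Fundc1 was lowest (0.00263 [0.000318, 0.00956]), and Rin2 followed (0.633). The main cluster of alveolar macrophages made up 68.7% of the class in NW and 67.8% in NK, but 45.3% in HSW and 35.0% in HSK, so these ratios also carry a change in make-up.

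Classical monocytes had higher Ly96, a partner of the endotoxin receptor (2.76 times [2.32, 3.29]), Ly6c2 (2.61 times) and Ifi202b (2.56 times) in HSW than NW, and lower Kdm1a (0.339), Cdk2ap1 (0.356) and Paxbp1 (0.360). In HSK against HSW, Cxcl10, an interferon-induced chemokine gene, was 0.458 [0.400, 0.523], Rasa4 0.396 and Phf11b 0.487, while Wdr3 (1.89 times), Atp5g2 (1.89 times) and Pqbp1 (1.77 times) led. The interferon list stood at -0.27 [-0.40, -0.22] with 28 of 33 lower and leukocyte adhesion at -0.32 [-0.46, -0.24] with 13 of 17 lower, whereas MHC class II stood at 0.38 [0.26, 0.44] with 8 of 11 higher; haemoglobin and surfactant transcripts stood at 0.24 [0.19, 0.65]. These ratios also carry a change in make-up: the cluster with Ly6c2 among its leading genes made up 52.1% of classical monocytes in NW, 74.8% in HSW and 80.7% in HSK, and the cluster with Irf7 and Oas2 among its leading genes the rest. Non-classical monocytes, with 4 cells in HSK, could not be compared in that library. In HSW against NW, with 62 cells in HSW, Ly96 (8.53 times [5.20, 14.3]), Zfp787 (4.76 times) and Smagp (3.93 times) led, Ppp6r3 (0.103 [0.0123, 0.383]), Tbkbp1 (0.156 [0.0316, 0.471]) and Pfkl (0.157) were lowest, and MHC class II genes stood at 0.65 [0.55, 0.80] with 6 of 8 higher.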

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

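In this part, the tests of a shift shared by the whole library, of RNA from other cells for the aryl hydrocarbon receptor genes, of a broad NRF2 response and of the rule that removed mixed cells were chosen after the result was seen, as were the removal of the unnamed sub-cluster and the equal weighting of subtypes.

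For 7 of the 10 genes named for the size of this difference, the HySu effect in endothelial cells went in opposite directions in the 2 genotypes with both counting intervals apart from no change; with 1 library per group this difference was not tested. Wdr43 (-1.41 in the knockout, 0.98 in wild type) was opposite too, but its wild-type interval held no change. Choice by the size of the difference favours opposite signs. Among these 7 genes, except for Fabp4, the genotypes stood further apart in normoxia than under HySu. The normoxia counts were low, with 5 UMIs in NW for Arl15, 3 for Mmd, 6 for Msantd4 and 15 for Hey1, and in NK 10 for Srek1ip1 and 8 for Mzt2. Fabp4 had a log2 ratio of 1.60 in the knockout and -4.25 in wild type, a difference of 5.85. Without the unnamed sub-cluster this difference turned to -0.76, on few UMIs. Srek1ip1 had 1.00 and -1.61, a difference of 2.61. Mzt2 had 1.09 and -1.37, a difference of 2.47. Arl15 had -1.71 and 1.41, a difference of -3.12. Mmd had -1.39 and 1.5006, a difference of -2.89. The Notch and BMP target Hey1 had -1.28 and 1.38, a difference of -2.66. Msantd4 had -1.02 and 1.37, a difference of -2.39. Hey1 and Mmd were among the leading genes of the general capillary sub-clusters. The share of these went from 16.0% in NW to 36.1% in HSW and from 31.0% in NK to 24.2% in HSK. However, the wild-type ratio of this share, 2.26, was 0 under the mixed-cell rule without leukocyte genes. With subtypes weighted equally the differences of Hey1 and Mmd were -2.47 and -2.42, but the unnamed sub-cluster was counted as general capillary there.

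Mitochondrially encoded OXPHOS genes were lower in endothelial cells of NK than NW, with a median log2 ratio of -0.37. With thinned cells, which left 30 endothelial cells in NW and 34 in NK, the median was -0.67. The lower values therefore did not come from the shallower cells alone. Thinning does not change the expected CPM of the cells that stay, so it cannot otherwise decide on depth. RNA from other cells is argued against, since the median was -0.36 with free RNA subtracted. A shift shared by the whole library stays open: the other 8 classes lay between -0.73 and -0.38, so the endothelial value was no larger than theirs. A library-wide technical shift and an effect of the knockout on all cells cannot be told apart, because genotype and library coincide.

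Cyp1a1, Cyp1b1, Nqo1 and Ahrr were higher with HySu in endothelial cells of both genotypes. RNA from other cells is argued against, since 4 of 4 genes had their highest level in endothelial cells of HSW, with Cyp1b1 at 2176 CPM against 102 in fibroblasts. Receptor activity raised by the treatment throughout the tissue stays open: at least 2 of 4 target genes had been predicted to be higher in fibroblasts of both genotypes and 1 of 4 was (Cyp1b1, 3.08 times and 5.36 times, against Tiparp at 0.665 and 0.943), but that bound was wrong, since Nqo1 and Ahrr had at most 10 UMIs per comparison there. In AT2 cells, Cyp1b1 was 30.05 and 55.5 times and Nqo1 3.38 [1.64, 7.64] and 4.42 [2.51, 8.39] times as high, and Ahrr 6.42 times [3.11, 14.5] in classical monocytes of HSW, but endothelial identity genes read higher in HSW than NW in both classes too (0.69 and 0.66), so RNA from endothelial cells is not excluded there. For a broad NRF2 response, 8 measured NRF2 target genes had a median log2 HSW to NW ratio of 0.40 [0.22, 0.82]. Most of them also belong to the antioxidant list, which was higher in the same comparison, so a median above 0 was likely. The set was not ranked among random lists or run in the knockout. It therefore does not decide whether such a response contributes. Whether SU5416 itself, hypoxia or neither acts on any of these genes was not tested, since both came together.

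Cell cycle genes were higher in endothelial cells of HSK than HSW. Cycling cells of another type were sought among cells already placed in the endothelial cluster, after cells with a second lineage had been removed. In the 24 cycling cells of both libraries, pan-endothelial transcripts stood at 0.729 [0.697, 0.761] of the level in other endothelial cells, above the preset bound. That selection made such a result likely, so it does not exclude cells of another type. A different mix of aerocyte, arterial, venous and capillary cells is argued against, since the median with subtypes weighted equally was 0.80. The unnamed sub-cluster was counted as general capillary there, so that weighting did not remove a shift between these. With the unnamed sub-cluster left out, the median stayed inside its counting interval of 0.50 to 0.92, although the ratio of Cenpf was smaller. The rule that removed mixed cells stays open: with Scrublet calls alone removed the median was 0.11, below the counting interval of 0.50 to 0.92. The higher cell cycle median may therefore come from which cells were removed, and a biological difference is not established.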

How the results depend on the processing

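Chosen after the data were seen were Scrublet calls alone removed, the mixed-cell level of 0.1, the rule without leukocyte genes, the common UMI minimum, equal subtype weights, mixed cells in the denominator and removal of the unnamed sub-cluster. No paired analysis was possible because each group had 1 library, and no test across groups was run. Over all alternatives, Fundc1 values kept their direction, with 48 inside the counting interval and 1 moved. Gene ratios stayed inside it in 1261 cases, moved in 140 and reversed in 7; list medians in 1047, 188 and 8; shares in 214, 146 and 2; depths in 4, 4 and 0.

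The cell cycle medians of endothelial cells changed with several alternatives. HSW against NW (1.47) was 0.81 with at least 100 UMIs, 0.78 without leukocyte genes, -0.10 with doublets kept and -0.18 with Scrublet calls alone removed. HSK against HSW (0.76) was 0.92 at the level of 0.1, 0.10 with doublets kept and 0.11 with Scrublet calls alone. HSK against NK (2.43) was 0.75 with at least 100 UMIs, 1.16 without the unnamed sub-cluster, -0.83 with doublets kept and -0.93 with Scrublet calls alone. These last settings also reversed Cenpf (-1.13 and -1.20) and Prc1 (-0.0751 and -0.15) in HSK against NK, and macrophage genes in HSK against HSW (-0.19 and -0.17). They held more endothelial cells, 147, 333, 440 and 182 with doublets kept. Doublets kept also put endothelial identity in HSK against NK at 0.0360.

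Mitochondrially encoded OXPHOS in NK against NW (-0.37) was -0.67 with thinned cells, and mesenchymal genes in HSW against NW reached 0.0213. Without the unnamed sub-cluster, Fabp4 in HSK against HSW was -2.405 and its difference of HySu effects -0.76, both on few UMIs. F3 in fibroblasts was 0.37 without leukocyte genes. The cell cycle median of interstitial macrophages in HSW against NW (-1.95) was -1.02 with the mean of cell CPM. The correlation of HySu effects (0.453) was 0.388 with free RNA subtracted, 0.630 with at least 100 UMIs, 0.581 with doublets kept, 0.373 with thinned cells, 0.559 with Scrublet calls alone and 0.332 with the common UMI minimum.

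The endothelial share ratio of HSW to NW (7.68) was 4.54 with doublets kept, 5.18 among non-immune cells and 4.90 with Scrublet calls alone. The venous share ratio (0.352) was 1.82 among non-immune cells, where the denominator holds all stromal and epithelial cells. The general capillary share ratio was 0 without leukocyte genes, since no HSW cell lay in the sub-cluster that took that name. Median UMIs in NW were 6311 over all deposited cells, against 6198.5 over kept cells. The filter on genes and mitochondrial UMIs took no cell of NW, so this change came from the removal of mixed cells and Scrublet calls. Except for this change and those of denominator and of naming, the cause was not tested.

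Marker gating left 0, 2, 2 and 0 endothelial cells and gave no value, nor did equal weights for subtypes with at least 30 cells. Thinning left 30, 34, 232 and 128 endothelial cells. NK against NW was the comparison with the fewest endothelial UMIs.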

Other observations

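The observations in this part come from comparisons that were planned, and none of their values were tested; no test in this part was chosen after a result was seen. Among lymphocytes, the cell cycle lists of B cells and of T and NK cells had opposite signs in HSW against NW. In B cells (116 in NW, 70 in HSW), genes of the interferon response were higher in HSW than NW, with a median log2 ratio of 0.63 [0.40, 0.94] and 19 of 25 members higher, among them the chemokine gene Cxcl10 (25.4 times [9.53, 95.3]), the antiviral genes Rsad2 (4.53 times) and Ifit3 (4.35 times), and Ly6a (4.00 times [3.61, 4.44]). Their MHC class I genes stood at 0.54 [0.42, 0.71] and their cell cycle genes at -1.10 [-1.41, -0.61]. In T and NK cells (198 and 130), cell cycle genes were higher, at 0.47 [0.34, 0.60] with 20 of 26 higher, including Aurkb (2.79 times) and Tyms (2.48 times). Their immediate early genes stood at -0.70 [-0.87, -0.58] (Fos 0.404), and this list also lay below the range of random lists in fibroblasts (-0.59), interstitial macrophages (-0.59) and B cells (-1.09). T and NK cells shifted between 2 clusters, the larger of which held 71.2% of them in NW and 52.3% in HSW.

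AT2 cells, which make surfactant, had lower mesenchymal (-1.04 [-1.24, -0.82]), contractile (-1.03), matrix (-0.89) and interferon genes (-0.74 [-0.88, -0.51], 23 of 26 lower) in HSW than NW. Outside the endothelium, AT2 cells included, mesenchymal medians were below 0 in 8 of 8 classes and contractile in 6 of 6. Matrix medians were below 0 in 7 of 7 and interferon in 6 of 8. Whether RNA from other cells moved these lists in AT2 cells was not tested. Edn1, the gene of the vasoconstrictor endothelin, was 3.24 times as high [1.503, 7.73] in these cells, on 31 UMIs against 9. Endothelial identity genes also read 0.69 [0.32, 0.91] in AT2 cells and 1.22 in alveolar macrophages in this comparison, and RNA from endothelial cells is not excluded there. AT2 cells fell into clusters that followed the treatment, with 1 cluster holding 20.7% of them in NW, 12.6% in NK, 79.0% in HSW and 86.5% in HSK. Ciliated cells made up 1.14% of kept cells in NW, 1.89% in NK, 2.77% in HSW and 3.12% in HSK. B cells made up 2.01% in NW, 2.40% in NK, 1.70% in HSW and 0.298% in HSK.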
